A study of Mus musculus with 9 samples.

How the data were processed

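Total RNA of mouse brain tissue was extracted with Trizol and made into libraries with the Illumina Stranded Total RNA Prep, per the labels. The authors aligned reads with HISAT2 2.1.0 and quantified genes with Cufflinks 2.2.1. The deposited table holds FPKM (fragments scaled to transcript length and library size) for each gene and library, with the lower and upper bounds of an interval around each FPKM value as the authors' program gave them. Read counts and library depths are not given in the sources used here, and neither are the genome build and annotation; gene identifiers and positions match GRCm38, with 22452 of 22482 identifiers found in GENCODE M21. Starts were moved to count from 1. By that annotation 21850 of the genes are protein-coding and 491 are immunoglobulin or T cell receptor segments, and 141 are of other types or not in that annotation, so few non-coding RNAs were analysed here. Symbols that a spreadsheet had turned into dates (26) were restored from the identifiers, 1 emptied entry was dropped, and 23 second entries of a repeated symbol were told apart by identifier.

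Samples were grouped as labelled: Sham, TBI and C-β-LG/DSF, 3 libraries each. Genes were kept when their FPKM was at least 0.5 in at least 3 of the 9 samples (14292 genes). Values were analysed as log2(FPKM + 0.5) in limma 3.58.1 under R 4.3.3, with 1 mean per group, 6 residual degrees of freedom, moderated variances with a mean trend, and two-sided tests adjusted by Benjamini-Hochberg within each comparison; genes at an adjusted p under 0.05 were called. The added 0.5 understates the differences of genes with low FPKM, and no fold is given against a group listed at 0. Log2 differences in the text are the first group minus the second, with the standard error of the fit. Intervals are 95% intervals of the fit for that gene alone. With 3 libraries against 3 an exact permutation test of a single gene cannot give a two-sided p under 0.1, so the calls rest on the variance shared across genes.

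Gene lists (38), covering pyroptosis, inflammation, cell types, brain regions and metabolism, were fixed before the data were examined, and the 36 with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01, adjusted over the 36 lists. The list of lymphocytes had 2 measured genes and that of abundant non-coding RNA had 1, so these were not tested. Because camera with a low preset correlation is liberal, the same test with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, are given beside it. With an estimated correlation no list passed in any of the 3 comparisons (smallest adjusted p 0.261, 0.502 and 0.359). By fry, 24 lists passed in TBI against Sham, 0 in C-β-LG/DSF against TBI and 17 in C-β-LG/DSF against Sham. The test and the median of a list differed in sign for striatal neurons in both comparisons with Sham and for neutrophils in C-β-LG/DSF against TBI. The means of a list per library were taken relative to the Sham mean of each gene.

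Named genes were chosen by a rule also fixed before the data were examined. For each of the first 2 comparisons it takes the 6 genes with the largest difference in each direction among those called, with a mean FPKM of at least 1 in the higher group and no overlap between the groups, and where too few are called the genes of smallest p under the same conditions, said not to pass; predicted genes are passed over. It adds all members of the pyroptosis list, with Gsdmd, Casp1, Nlrp3, Il1b and Il18 always given, and the 2 or 3 members of smallest p in each list described. For C-β-LG/DSF against Sham it takes 3 genes in each direction and the same 5 genes. A few genes that the rule takes are not reported here. Genes outside this rule are said to be chosen after their values were seen. Marker lists of the thalamus, of the hypothalamus and midbrain, of cortical layers and of the circadian clock were assembled after the values had been seen, and no list test was run on them. The thalamic list, chosen from these same libraries, also gave a score used as a covariate. Values of p from that fit depend on this choice.

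The share of genes changed in TBI that moved back was compared with 100 simulated data sets. In these, C-β-LG/DSF and TBI both had the observed TBI means. The share was also compared with 100 in which no group differed, where the 3836 genes of smallest p were taken. In both, the spread was that of the data, pooled over the 3 groups. The whole procedure was tested on simulated data with noise independent between genes and alike in all groups. Of genes given a 2-fold change, 80% were called in TBI against Sham, 66% in C-β-LG/DSF against TBI and 80% in C-β-LG/DSF against Sham. Of genes given a 1.5-fold change, 28%, 26% and 36% were called. The spread was the same in all 3 comparisons, so differences between these shares do not rank them. Genes of the data are correlated and TBI libraries varied more, so the shares do not give the power of the real comparisons. The alternatives tried were pseudocounts of 0.1 and 1, no filter and a stricter filter on low values, median-of-ratios scaling, rescaling to equal totals (TPM), quantile normalization, a fit of only the 2 groups compared, the replicate number as a block, other variance models, a 2-fold minimum and leaving out each library in turn. A marker score of the thalamus as a covariate, and leaving out the 3 libraries with thalamic markers, were added after the data had been seen. Tests that need read counts were planned for the case that counts were found and were not run. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.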

Results

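RNA from mouse brain was sequenced in 3 groups of 3 libraries each. In the Sham group the skull and the dura were opened and the brain was left intact. The TBI group received a traumatic brain injury by a falling weight. The third group received C-β-LG/DSF, the nanoparticle preparation of this series, through a tail vein after the injury. Tissue came from the injured site, or from the matching site in Sham, and the stated interest was in genes of pyroptosis (inflammatory cell death by gasdermin pores) and inflammation. Neither the time after injury nor the dose is given in the sources used here. The labels do not say whether the libraries of a group came from separate animals, so every p-value measures only the spread between these samples.

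The values are FPKM, and the number of fragments per library is not given. FPKM totals ran from 406274 in C-β-LG/DSF 3 to 445404 in Sham 2, and the depths estimated relative to Sham 1 ran from 0.933 to 1.09. Between 12566 and 13312 genes per library had an FPKM of 1 or more. The authors' interval around a value had a median half-width of 45.9% to 46.8% of it at an FPKM of 10 to 100, and of 106% to 107% at an FPKM of 1 to 2. Across genes, libraries of 1 group correlated with r = 0.989 to 0.990 in Sham, 0.946 to 0.972 in TBI and 0.976 to 0.986 in C-β-LG/DSF; genes are not independent replicates. The first principal component held 54.5% of the variance and separated Sham (-44.6 to -39.3) from the injured libraries (5.83 to 54.4), with TBI 1 at the far end.

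The comparison of TBI with Sham asked which genes the injury changed at its site. Genes of phagocytic microglia, reactive astrocytes, complement and chemokines rose, and genes of neurons and neuronal activity fell. Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050), which encodes the matrix protein osteopontin, rose from 1.01 ± 0.997 FPKM (SD, n = 3) to 672 ± 584 FPKM (SD, n = 3), a log2 difference of 8.65 (SE 0.70, adjusted p = 0.000466). Lyz2, the lysozyme of myeloid cells, rose from 3.81 ± 0.562 FPKM (SD, n = 3) to 292 ± 123 FPKM (SD, n = 3), a log2 difference of 6.01 (SE 0.32). The other genes with the largest increases were Gpnmb (5.54, SE 0.71), a glycoprotein of phagocytes, the galectin gene Lgals3 (5.23, SE 0.60), the lipocalin gene Lcn2 (5.13, SE 0.49) and the heme oxygenase gene Hmox1 (4.62, SE 0.70). The largest decreases were in Tcap (-2.71, SE 0.38), Egr2 (-2.51, SE 0.41), Nr4a1 (-2.33, SE 0.42), Tnnc1 (-2.26, SE 0.42), Lamp5 (-2.25, SE 0.25) and Egr1 (-2.20, SE 0.42). Egr1, Egr2 and Nr4a1 are transcription factor genes induced by neuronal activity, and Tcap and Tnnc1 encode proteins of the muscle sarcomere. Adjusted p for these 12 genes was at most 0.00563. That all TBI libraries lay on 1 side of all Sham libraries was a condition of their choice.

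Of 14292 genes tested with limma, 3836 passed an adjusted p of 0.05, 2127 higher and 1709 lower in TBI, and 1149 of them differed at least 2-fold (938 higher and 211 lower). After quantile normalization the split was 1581 higher and 1895 lower. In 6134 genes (42.9%) the TBI and Sham libraries did not overlap, against 10% by chance. The count was 2388 without Sham 1, 2550 without Sham 2 and 2242 without Sham 3.

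Microglial genes rose in TBI. All 25 measured genes of phagocytic and disease-associated microglia rose, also when adjusted over the list alone (median log2 difference 2.07, camera adjusted p = 1.39e-16), among them Spp1, Lyz2 and the tetraspanin gene Cd9 (1.83, SE 0.11). Of the homeostatic microglia list, 16 of 19 genes rose (17 when adjusted over the list alone; median 1.48, camera adjusted p = 6.56e-10), among them Adgrg1 (1.07), the growth factor receptor gene Csf1r (1.70) and Sall1 (1.01). With an estimated correlation between genes the adjusted p = 0.261 for both lists. In the list of infiltrating monocytes and macrophages 15 of 21 genes rose and none fell (16 and 1 when adjusted over the list alone; median 2.03, camera adjusted p = 2.55e-07; adjusted p = 0.288 with an estimated correlation), including Pf4 (1.90) and S100a4 (3.22). TBI 1 lay highest in these 3 lists, with means of 3.29, 1.51 and 2.59 on the log2 scale against 2.12, 1.03 and 1.06 in TBI 3.

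The inflammatory gene groups moved the same way. In the complement list 14 of 20 genes rose (14 when adjusted over the list alone; median 1.62, camera adjusted p = 6.89e-08), including C4b (3.26, SE 0.15), the smallest p of all genes, Itgax (1.91) and C1qc (3.01). Cytokines and chemokines had 15 of 19 genes higher and 1 lower (15 and 2 when adjusted over the list alone; median 1.98, camera adjusted p = 1.25e-05), among them Cxcl16 (2.54), Ccl4 (2.26) and Ccl8, which was listed at 0 in Sham and averaged 1.68 ± 0.509 FPKM (SD, n = 3) in TBI. In the Toll-like receptor and NF-kB list 18 of 31 genes rose (21 when adjusted over the list alone; median 0.85, camera adjusted p = 1.04e-08), with Tlr2 (2.92), the adhesion molecule gene Icam1 (2.12) and Nfkb2 (1.44) at the smallest p. Antigen presentation genes rose in 12 of 22 cases (15 when adjusted over the list alone; median 1.17, camera adjusted p = 8.97e-07), including the class II genes H2-Aa (1.91) and H2-Ab1 (2.04) and the costimulator gene Cd86 (1.90). With an estimated correlation the adjusted p was 0.261 for complement, 0.277 for cytokines, 0.288 for the Toll-like receptor list and 0.288 for antigen presentation.

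Astrocyte genes also rose. Of the reactive astrocyte list, 20 of 27 genes rose (23 when adjusted over the list alone; median 1.62, camera adjusted p = 3.09e-11; adjusted p = 0.270 with an estimated correlation), among them Serpina3n (2.93, SE 0.16), Lcn2 and the filament gene Gfap, which went from 42.3 ± 2.45 FPKM (SD, n = 3) to 1120.0 ± 521 FPKM (SD, n = 3). Of the homeostatic astrocyte list, 10 of 20 genes rose (10 when adjusted over the list alone; median 0.50, camera adjusted p = 3.22e-05; adjusted p = 0.288 with an estimated correlation), including the water channel gene Aqp4 (2.11), Gja1 (0.92) and Mlc1 (0.58). Proliferation genes of the cell cycle list rose in 24 of 32 cases and fell in 1 (28 and 2 when adjusted over the list alone; median 1.80, camera adjusted p = 1.54e-08; adjusted p = 0.379 with an estimated correlation), with Ube2c (3.80), Cdk1 (3.23) and Top2a (2.93) as examples. TBI 1 had the highest means of the reactive astrocyte list (2.75, against 1.74 and 1.58) and of the cell cycle list (2.70, against 1.45 and 1.13).

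Neuronal genes fell. Of the general neuron list, 11 of 20 genes fell (11 when adjusted over the list alone; median -0.55, camera adjusted p = 9.43e-06), including the nuclear protein gene Rbfox3 (-0.94), Vsnl1 (-1.04) and the synaptic gene Snap25 (-1.10). In the excitatory list 13 of 23 genes fell and 1 rose (14 and 1 when adjusted over the list alone; median -0.57, camera adjusted p = 2.93e-06), among them the cortical transcription factor gene Rorb (-1.43) and the glutamate receptor gene Gria3 (-0.81). The inhibitory list had 7 of 21 genes lower (8 when adjusted over the list alone; median -0.55, camera adjusted p = 1.76e-05), including Vip (-1.41) and Npy (-1.25). Of the immediate early genes, 17 of 24 fell and 1 rose (19 and 2 when adjusted over the list alone; median -1.35, camera adjusted p = 1.37e-06); Egr3 fell (-1.59), and the stress-induced gene Atf3 rose by 2.62. With an estimated correlation the adjusted p was 0.288 for the general neuron, inhibitory and immediate early gene lists and 0.261 for the excitatory list. Beside the neuronal lists, 15 markers of cortical layers averaged between -0.75 and -0.46 in the TBI libraries and 13 hippocampal markers between 0.89 and 1.71, on the log2 scale relative to Sham. Marker lists of the thalamus and of the hypothalamus and midbrain, assembled after the values were seen, stood at 2.55 and 2.39 in TBI 3, at 0.20 and 0.10 in TBI 1 and at 0.49 and 0.34 in TBI 2.

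**Figure D1:**
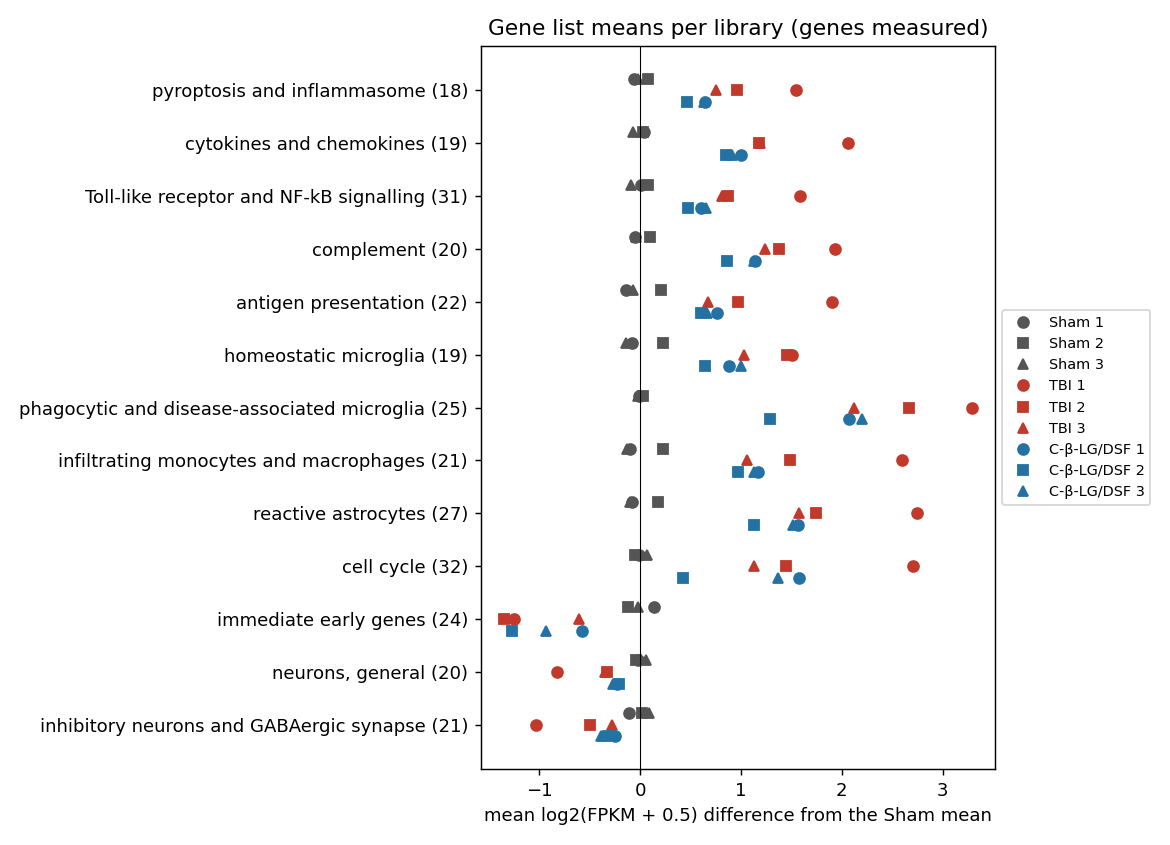
Mean log2(FPKM + 0.5) difference from the Sham mean (horizontal axis) over the measured genes of 13 lists (vertical axis, number of genes in parentheses), 1 symbol per library; circles, squares and triangles are libraries 1, 2 and 3 of Sham (gray), TBI (red) and C-β-LG/DSF (blue). For pyroptosis and inflammasome genes the TBI libraries lie between 0.75 and 1.55 and the C-β-LG/DSF libraries between 0.46 and 0.65.

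Pyroptosis genes rose as a group in TBI. Of 18 measured genes of the pyroptosis and inflammasome list, 12 rose, none fell and 17 had a positive difference (14 rose when adjusted over the list alone; median 1.003, camera adjusted p = 1.77e-06; adjusted p = 0.261 with an estimated correlation). Gsdmd (ENSMUSG00000022575.4, chromosome 15, 75862327 to 75867408), the pore-forming gasdermin, rose from 1.19 ± 0.0825 FPKM (SD, n = 3) in Sham to 5.74 ± 2.27 FPKM (SD, n = 3) in TBI, a log2 difference of 1.83 (SE 0.22, adjusted p = 0.00117). Pycard (ENSMUSG00000030793.4, chromosome 7, 127989708 to 127993867), the inflammasome adaptor ASC, rose from 1.55 ± 0.867 FPKM (SD, n = 3) to 15.1 ± 11.1 FPKM (SD, n = 3), a log2 difference of 2.77 (SE 0.48, adjusted p = 0.00377). Beside the mean of 1.08 for this list, the means of the homeostatic microglia, monocyte and phagocytic microglia lists were 1.33, 1.71 and 2.69, with TBI 1 highest in each. Naip2 (1.53), Naip5 (1.23), P2rx7 (1.36), Ninj1 (1.07) and Txnip (0.96) rose as well. The calls of 5 further members ended when 1 library was left out: Casp8 (1.60) without Sham 1 or Sham 3, Il1a (0.88) without Sham 3 or TBI 1, Gbp5 (0.96) without Sham 1, Sham 2 or TBI 1, Zbp1 (1.36) without any Sham library or TBI 1, and Gbp2 (1.003) without any Sham library, TBI 1 or TBI 3. Quantile normalization also ended the calls of Il1a, Gbp5, Zbp1 and Gbp2. The replicate number as a block ended those of Gbp5 and Gbp2. No filter, and a fit of only the 2 groups, each ended those of Gbp5, Zbp1 and Gbp2, and a pseudocount of 1 ended that of Zbp1.

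The other genes always given did not pass the test in TBI. Casp1 (ENSMUSG00000025888.5, chromosome 9, 5298517 to 5307265), the inflammatory caspase, averaged 1.22 ± 0.187 FPKM (SD, n = 3) in Sham and 2.51 ± 1.24 FPKM (SD, n = 3) in TBI (log2 difference 0.71, SE 0.31, adjusted p = 0.121). TBI 3 was at 1.08 FPKM, and without it the Casp1 difference was 1.12 (adjusted p = 0.00202). With a thalamic marker score as a covariate it was 1.14 (adjusted p = 0.00691). Nlrp3 (ENSMUSG00000032691.14, chromosome 11, 59541568 to 59566956), an inflammasome sensor, averaged 0.296 ± 0.260 FPKM (SD, n = 3) in Sham and 1.07 ± 0.648 FPKM (SD, n = 3) in TBI (log2 difference 0.95, SE 0.32, adjusted p = 0.0579). This difference passed without TBI 3 (1.22, adjusted p = 0.0181), without Sham 2 (1.20, adjusted p = 0.0419), after rescaling to equal totals (1.35, adjusted p = 0.0482) and with the covariate (1.26, adjusted p = 0.0183). Il18 (ENSMUSG00000039217.13, chromosome 9, 50554827 to 50581840) averaged 14.8 ± 1.37 FPKM (SD, n = 3) and 17.0 ± 0.606 FPKM (SD, n = 3), a log2 difference of 0.20 (SE 0.17, adjusted p = 0.42). Il1b (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139) was too low to be tested, at 0.202 ± 0.0920 FPKM (SD, n = 3) in Sham and 0.693 ± 0.579 FPKM (SD, n = 3) in TBI. The authors' intervals of Il1b and of Nlrp3 included 0 in every library. Those of Casp1 included 0 in all Sham libraries, TBI 3, C-β-LG/DSF 1 and C-β-LG/DSF 2. Those of Gsdmd included 0 in all Sham libraries, with upper bounds of at most 2.72. Only in TBI 1 (lower bound 3.11) did the Gsdmd interval lie above those of Sham.

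**Figure D2:**
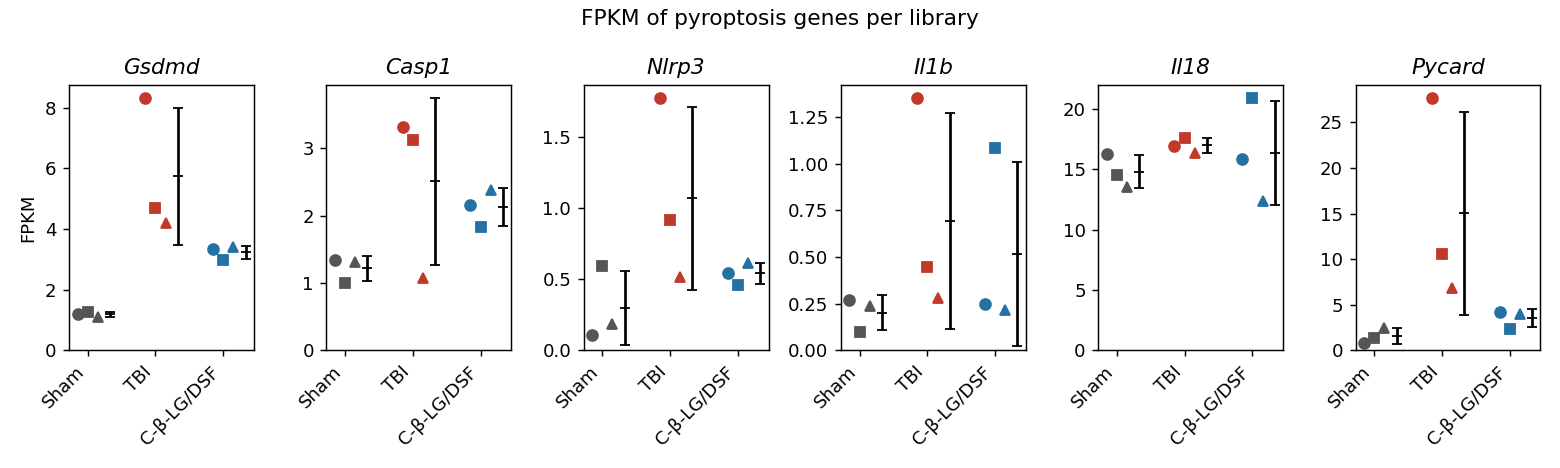
FPKM (vertical axis, starting at 0) of 6 pyroptosis genes in the Sham (gray), TBI (red) and C-β-LG/DSF (blue) libraries; circles, squares and triangles are libraries 1, 2 and 3, and each bar is the mean ± SD of 3 libraries. Gsdmd lies between 1.10 and 1.25 FPKM in Sham, 4.19 and 8.34 FPKM in TBI and 2.99 and 3.40 FPKM in C-β-LG/DSF.

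The comparison of C-β-LG/DSF with TBI asked whether the preparation altered expression at the injured site, pyroptosis and inflammation genes first. Gsdmd was lower in all C-β-LG/DSF libraries than in all TBI libraries, at 3.24 ± 0.217 FPKM (SD, n = 3) against 5.74 ± 2.27 FPKM (SD, n = 3), but the difference did not pass the test over all genes (log2 difference -0.68, 95% interval -1.17 to -0.19, adjusted p = 0.394). Pycard was at 3.52 ± 0.979 FPKM (SD, n = 3) against 15.1 ± 11.1 FPKM (SD, n = 3) (log2 difference -1.75, SE 0.48, adjusted p = 0.394), again with no overlap. In Casp1 the difference was -0.10 (95% interval -0.79 to 0.60, adjusted p = 0.906), at 2.13 ± 0.276 FPKM (SD, n = 3) in C-β-LG/DSF, and it turned positive without TBI 1 (0.13), without TBI 2 (0.09) and after quantile normalization (0.01). In Nlrp3 it was -0.51 (95% interval -1.25 to 0.22, adjusted p = 0.513), at 0.542 ± 0.0766 FPKM (SD, n = 3). Nlrp3 was at 1.78 FPKM in TBI 1 against 0.917 in TBI 2 and 0.514 in TBI 3.

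Il18 averaged 16.4 ± 4.33 FPKM (SD, n = 3) in C-β-LG/DSF, a difference from TBI of -0.08 (95% interval -0.45 to 0.29, adjusted p = 0.845) that turned positive without C-β-LG/DSF 3 (0.10). Il1b was at 0.515 ± 0.492 FPKM (SD, n = 3) and was not tested. In the pyroptosis list 17 of 18 genes had lower values in C-β-LG/DSF and none passed the test, over all genes or adjusted over the list alone. The list as a whole was lower (median -0.50, camera adjusted p = 3.98e-05; adjusted p = 0.502 with an estimated correlation). The list's median was -0.24 without TBI 1, where Gsdmd was highest, at 8.34 FPKM.

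No gene passed in C-β-LG/DSF against TBI: limma gave 0 of 14292 at an adjusted p of 0.05 (smallest 0.361). At an unadjusted p under 0.05 there were 1693, where chance gives 715 on average. Genes are not independent, and the spread of that chance count was not estimated, so the excess is no evidence of an effect. The count of 1693 became 879 without TBI 1, 1011 without C-β-LG/DSF 2, 1118 when only these groups were fitted and 3385 without TBI 3. The 2 groups did not overlap in 2180 genes (15.3%, against 10% by chance). Among the genes with the smallest p, none of which pass, the higher ones in C-β-LG/DSF were Cdhr1 (1.80, SE 0.33), Tmem28 (0.48, SE 0.09), Ndst4 (0.93, SE 0.18), the netrin receptor gene Unc5d (0.68, SE 0.14), the potassium channel gene Kcnd3 (0.64, SE 0.13) and Tmem68 (0.46, SE 0.10). The lower ones were Adgrg5 (-1.20, SE 0.17), Cd9 (-0.76, SE 0.11), Ctla2a (-1.22, SE 0.20), Slc37a2 (-1.68, SE 0.27), Eci2 (-0.46, SE 0.08) and Akr1b8 (-1.32, SE 0.23). Adjusted p was 0.361 for Adgrg5 and Cd9 and 0.394 for the others. Cd9 averaged 68.3 ± 7.16 FPKM (SD, n = 3) in C-β-LG/DSF, 116 ± 10.9 FPKM (SD, n = 3) in TBI and 32.1 ± 3.32 FPKM (SD, n = 3) in Sham.

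As groups, microglial, inflammatory and glial genes were lower in C-β-LG/DSF than in TBI. In each list named here, no gene passed the test over all genes. Phagocytic and disease-associated microglia genes were lower in 24 of 25 cases, 15 of them when adjusted over the list alone (median -0.80, camera adjusted p = 7.45e-12; adjusted p = 0.502 with an estimated correlation), with Cd9, Lyz2 (-1.68) and Fabp5 (-1.36) at the smallest p. Homeostatic microglia genes were lower in 18 of 19 cases, 0 of them when adjusted over the list alone (median -0.45, camera adjusted p = 4.76e-06; adjusted p = 0.502 with an estimated correlation), among them Gpr34 (-0.77), Sall1 (-0.43) and Csf1r (-0.69). In the monocyte and macrophage list 16 of 21 genes were lower, 3 of them when adjusted over the list alone (median -0.87, camera adjusted p = 0.000406; adjusted p = 0.565 with an estimated correlation), including Pf4 (-1.34), the lectin gene Clec4n (-1.71) and the arginase gene Arg1 (-2.13). Reactive astrocyte genes were lower in 23 of 27 cases, 1 of them when adjusted over the list alone (median -0.74, camera adjusted p = 2.52e-05; adjusted p = 0.563 with an estimated correlation), with Serpina3n (-0.84), Srgn (-1.04) and Steap4 (-0.94) as examples. Without TBI 1 the mean difference went from -0.84 to -0.55 for phagocytic microglia, from -0.49 to -0.40 for homeostatic microglia, from -0.62 to -0.18 for monocytes and macrophages and from -0.62 to -0.26 for reactive astrocytes.

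Signalling genes had lower values too. In the Toll-like receptor and NF-kB list 30 of 31 genes were lower, 0 of them when adjusted over the list alone (median -0.54, camera adjusted p = 1.32e-08), among them Tlr2 (-1.04), Birc3 (-0.65) and Nfkbia (-0.35). Cytokines and chemokines were lower in 16 of 19 cases, 3 of them when adjusted over the list alone (median -0.58, camera adjusted p = 0.000283), including Cxcl16 (-1.35), Ccl6 (-1.49) and the receptor antagonist gene Il1rn (-1.50), which was listed at 0 in Sham. Complement genes were lower in 18 of 20 cases, 0 of them when adjusted over the list alone (median -0.40, camera adjusted p = 9.78e-05), with Itgax (-0.73), C1qa (-0.94) and C1s1 (-0.74) at the smallest p. For these 3 lists the adjusted p = 0.502 with an estimated correlation. Antigen presentation genes were lower in 20 of 22 cases, 3 of them when adjusted over the list alone (median -0.48, camera adjusted p = 2.10e-05; adjusted p = 0.563 with an estimated correlation), among them H2-Ab1 (-1.10), H2-K1 (-1.38) and H2-Aa (-0.61). Leaving out TBI 1 moved the mean difference from -0.51 to -0.27 for the Toll-like receptor list, from -0.56 to -0.26 for cytokines, from -0.47 to -0.26 for complement and from -0.51 to -0.15 for antigen presentation.

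General neuron genes had higher values in 19 of 20 cases in C-β-LG/DSF than in TBI, 0 of them when adjusted over the list alone (median 0.26, camera adjusted p = 1.26e-05; adjusted p = 0.502 with an estimated correlation), with Map2 (0.45), Syp (0.34) and Elavl4 (0.47) at the smallest p. Inhibitory neuron genes were higher in 17 of 21 cases, 0 of them when adjusted over the list alone (median 0.26, camera adjusted p = 0.00191; adjusted p = 0.563 with an estimated correlation), among them Reln (0.99). TBI 1 had the lowest mean in both lists, and without it the mean difference went from 0.27 to 0.11 for general neuron genes and from 0.28 to 0.07 for inhibitory neuron genes. Immediate early genes went both ways and the list did not pass (median 0.21, camera adjusted p = 0.062). In this list Atf3 was lower (-1.41) and the growth factor gene Bdnf (0.52) and Fosl2 (0.45) were higher. Thalamic markers stood at 2.11 in C-β-LG/DSF 2 and 1.54 in C-β-LG/DSF 3, as in TBI 3, and at 0.36 in C-β-LG/DSF 1, on the log2 scale relative to Sham.

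Of the 36 lists tested, 24 passed with the preset correlation in C-β-LG/DSF against TBI, 20 lower and 4 higher. With an estimated correlation 0 passed, and by fry 0 passed (smallest adjusted p = 0.186). Splits of these libraries that mix the 2 groups passed 16 to 25 lists with the preset correlation, so passing it does not show an effect of C-β-LG/DSF. In 9 lists, pyroptosis among them, the mean of every C-β-LG/DSF library lay below that of every TBI library, and TBI 1 was the highest TBI library in 22 lists. On average 27 lists were lower in C-β-LG/DSF than in TBI, and 25 without TBI 1.

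**Figure D3:**
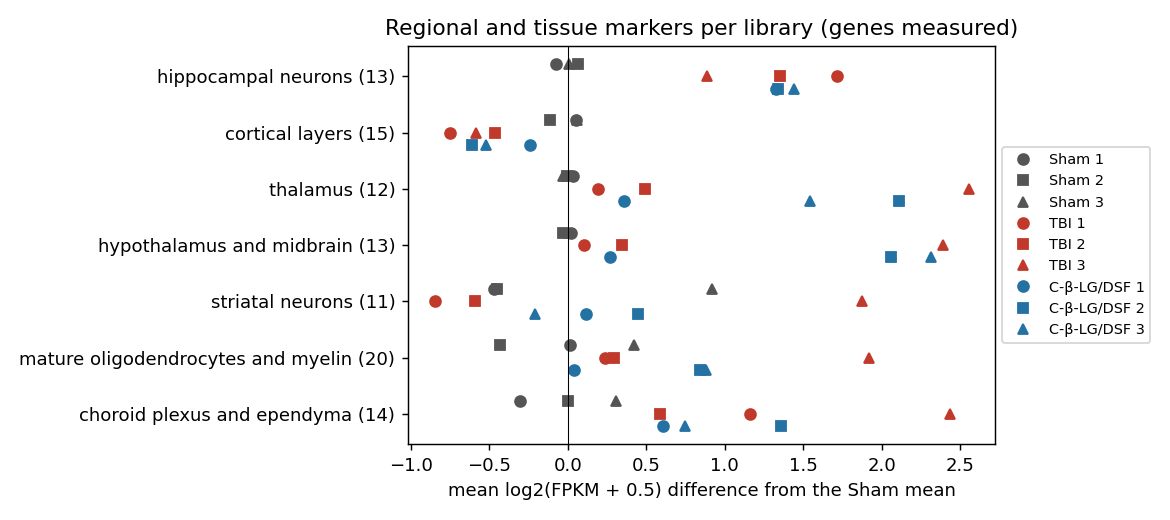
Mean log2(FPKM + 0.5) difference from the Sham mean (horizontal axis) over the measured marker genes of 7 brain regions and tissues (vertical axis, number of genes in parentheses), 1 symbol per library; circles, squares and triangles are libraries 1, 2 and 3 of Sham (gray), TBI (red) and C-β-LG/DSF (blue). Thalamic markers lie at 1.54 or above in TBI 3 and C-β-LG/DSF 2 and 3 and at 0.49 or below in the other 6 libraries.

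The genes that differed between TBI and Sham were also followed into the treated group. In these genes the injury was not separated from the part of the brain in the pieces. Of the 3836 genes changed in TBI, 84% differed between C-β-LG/DSF and TBI in the direction back toward Sham. Both differences use the TBI libraries, so opposite signs arise by chance as well: in 100 simulations with C-β-LG/DSF equal to TBI the share had a median of 62.1% and a 95% range of 25.8% to 87.5%, and 6 were as large as observed. With no effect in any group the median was 84.9%. The covariance of the 2 differences was -0.114, within the 95% range of -0.167 to 0.049 in the simulations with C-β-LG/DSF equal to TBI (mean -0.037) and outside that of -0.098 to 0.020 in those with no effect (mean -0.027). The observed share is therefore not beyond what shared libraries give.

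The comparison of C-β-LG/DSF with Sham asked what remained changed in treated injured tissue. Spp1 (7.08, SE 0.70, adjusted p = 0.00129), Lyz2 (4.33, SE 0.32, adjusted p = 0.000733) and Gpnmb (4.20, SE 0.71, adjusted p = 0.007) rose most, as in TBI. Lamp5, a marker of upper cortical layers, fell by 2.12 on the log2 scale (SE 0.25, adjusted p = 0.00218). Cwc22 (ENSMUSG00000027014.14, chromosome 2, 77881159 to 77946375), a splicing factor gene, averaged 10.9 ± 12.4 FPKM (SD, n = 3) against 74.4 ± 21.6 FPKM (SD, n = 3) in Sham, a log2 difference of -3.24 (SE 0.63, adjusted p = 0.0119) whose call ended without Sham 3 (adjusted p = 0.051) or C-β-LG/DSF 3 (adjusted p = 0.0519). Tnnc1 differed by -2.06 (SE 0.42, adjusted p = 0.0149), a call that ended without Sham 2 (adjusted p = 0.0572) or Sham 3 (adjusted p = 0.0609).

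Gsdmd stayed above Sham in C-β-LG/DSF, with a log2 difference of 1.15 (SE 0.22, adjusted p = 0.0112), a call that ended without C-β-LG/DSF 3 (1.12, adjusted p = 0.0527). Differences in Casp1 (0.61, SE 0.31, adjusted p = 0.219), Nlrp3 (0.43, SE 0.32, adjusted p = 0.407) and Il18 (0.11, SE 0.17, adjusted p = 0.69) did not pass, and that of Il18 was -0.08 without C-β-LG/DSF 2. Casp1 passed when only these groups were fitted (0.61, adjusted p = 0.0255) and with the thalamic marker score as a covariate (1.15, adjusted p = 0.0166). In the pyroptosis list 3 of 18 genes rose (3 when adjusted over the list alone; median 0.67, camera adjusted p = 0.000301; adjusted p = 0.359 with an estimated correlation), with a median of 0.38 after quantile normalization (camera adjusted p = 0.00769). Phagocytic and disease-associated microglia genes rose in 16 of 25 cases (23 when adjusted over the list alone; median 1.34, camera adjusted p = 1.30e-13), reactive astrocyte genes in 12 of 27 (20 when adjusted over the list alone; median 1.08, camera adjusted p = 5.66e-10) and complement genes in 11 of 20 (12 when adjusted over the list alone; median 1.03, camera adjusted p = 1.49e-06). Immediate early genes fell in 13 of 24 cases and rose in 1 (16 and 1 when adjusted over the list alone; median -1.24, camera adjusted p = 7.34e-06). For these 4 lists the adjusted p = 0.359 with an estimated correlation.

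In C-β-LG/DSF against Sham 1895 of 14292 genes passed with limma, 911 higher and 984 lower, or 1419 higher and 717 lower after rescaling to equal totals (TPM). In 6154 genes (43.1%) the libraries did not overlap, against 10% by chance. The count was 825 without Sham 1, 971 without Sham 2, 794 without Sham 3, 996 without C-β-LG/DSF 2 and 660 without C-β-LG/DSF 3; it was 271 without TBI 3, C-β-LG/DSF 2 and C-β-LG/DSF 3, the 3 libraries with thalamic markers. Fitting only C-β-LG/DSF and Sham gave 3444 genes, and fitting only TBI and Sham gave 2880. Which injured group has more changed genes thus depends on the fit. Of the genes higher than Sham in the main fit, 775 were shared with TBI, and of the lower ones 863. Both comparisons use the same Sham libraries, which raises this overlap, and the Sham libraries are too few to be divided between them. The differences of all genes correlated with r = 0.872, inside the 95% range of -0.372 to 0.937 in simulations with no effect in any group. Their covariance of 0.271 lay above its range of -0.013 to 0.099 there and below that of 0.290 to 0.617 in simulations with C-β-LG/DSF equal to TBI. The latter simulations take the observed TBI means, noise included, as the true ones and add noise again, which raises their covariance. Lying below their range therefore does not show that C-β-LG/DSF differs from TBI.

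**Figure D4:**
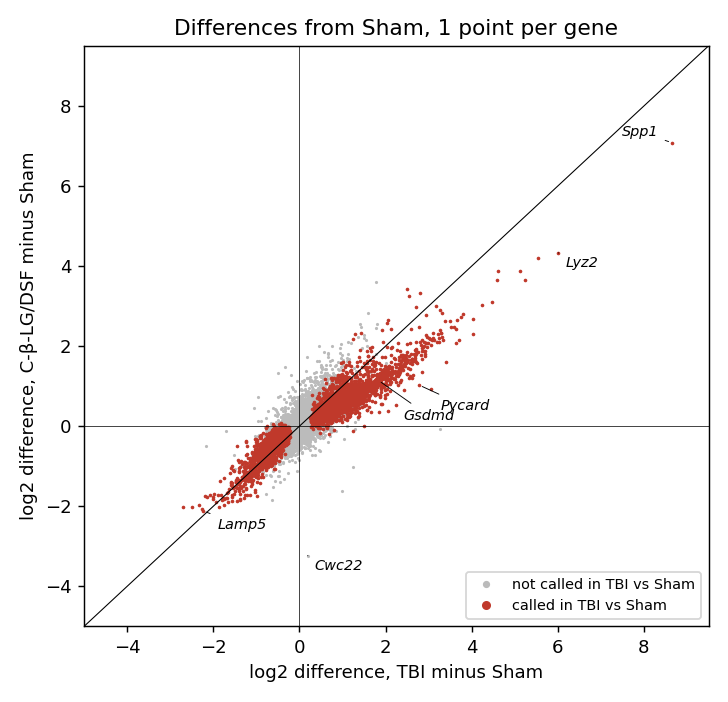
Log2 difference from Sham in TBI (horizontal axis) and in C-β-LG/DSF (vertical axis) of the genes tested, 1 point per gene, red for the 3836 genes called in TBI against Sham and gray for the others; the diagonal marks equal differences. Spp1 lies at 8.65 and 7.08, and Cwc22 stands apart below the others at -3.24 in C-β-LG/DSF; both axes share the Sham libraries.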

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

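The 2 alternatives that use thalamic markers were chosen after the results were seen; the others were planned. Over all alternatives, the log2 differences of the 126 genes followed for TBI against Sham kept their direction, and 2241 of 2372 values also kept their side of the threshold (104 lost the call, 27 gained it). For C-β-LG/DSF and TBI 2443 of 2459 values, for 131 genes, did both, 1 gained a call and 15 changed sign. For C-β-LG/DSF and Sham 177 of 188 values, for 10 genes, did both, 8 lost the call, 2 gained it and 1 changed sign. Gene counts under the alternatives not given here stayed within 1.5 times the reported ones, and no scaling moved the median of all genes by more than 0.1.

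With an estimated correlation 0 lists passed in each of the 3 comparisons, and by fry 0 passed in C-β-LG/DSF against TBI and 17 in C-β-LG/DSF against Sham. Both allow more correlation between genes than the preset. Because fry also drops the comparison with other genes, the reasons for its lower counts were not separated. The counts with a 2-fold minimum, a stricter rule, were 1149 genes in TBI against Sham and 594 in C-β-LG/DSF against Sham. Fitting only the 2 groups gave 2880 genes in TBI against Sham and 3444 in C-β-LG/DSF against Sham. In the main fit these counts were 3836 and 1895, so their order was reversed. The main fit shares 1 spread per gene over all 3 groups, and libraries correlated least within TBI. The cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 2242 to 4373 genes in TBI against Sham, 660 to 1538 in C-β-LG/DSF against Sham and 0 to 2 in C-β-LG/DSF against TBI, and a share moved back of 77% to 88.7%. Without TBI 3 the 2 genes were Miip (-1.23) and Ctla2a (-1.45), and without C-β-LG/DSF 1 the single gene was Cwc22 (-4.29). With no filter, C-β-LG/DSF against TBI gave 2 genes, Pla2g2e (-1.04) and the predicted gene Gm6594 (-1.50), and a variance model without a trend gave 1, Gm6594 (-1.50); the cause was not tested. These genes, but for Ctla2a and Cwc22, fall outside the naming rule and are named for completeness after their values were seen. Without TBI 3, C-β-LG/DSF 2 and C-β-LG/DSF 3 the counts were 1 (Rps3a1, -2.39) in C-β-LG/DSF against TBI and 271 in C-β-LG/DSF against Sham, from fewer samples, and the share moved back was 90.8%; C-β-LG/DSF then has 1 library, assumed to vary like the other groups.

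Changes of sign were all in genes that pass no test in that comparison, and the cause was not tested. In C-β-LG/DSF against TBI, quantile normalization gave 0.008 for Casp1 and 0.066 for mt-Nd5, and the thalamic covariate gave 0.006 for Casp1. Leaving out 1 library gave ranges of -0.51 to 0.13 for Casp1, -0.27 to 0.10 for Il18, 0.00 (-0.002) to 0.21 for Gsdme, -0.56 to 0.025 for Gbp2, -0.28 to 1.66 for S100a9, -0.52 to 0.044 for Car2 and -0.45 to 0.013 for mt-Nd3. Without the 3 libraries with thalamic markers the values were -1.46 for S100a9, 0.064 for Cenpf, 0.29 for Ppp1r1b and -0.33 for Cabp7. Against Sham, the C-β-LG/DSF difference of Il18 ranged from -0.076 to 0.29 when 1 library was left out.

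No clear pairing by replicate number was seen. Of 9 same-number pairs 2 correlated above 0.1 (range -0.095 to 0.326), and 3 of 9 libraries had their own number as the best partner. So few libraries cannot exclude a pairing. The labels also carry other sample codes, and pairing by those was not tested. With the replicate number as a block, 3519, 0 and 1627 genes and 27, 28 and 28 lists passed, and the share was 84.1%. Depth limits low genes most: at an FPKM of 1 to 2 the authors' interval spans about the value itself on each side. Tests that need read counts were not run.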

Other observations

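All tests of explanations below were chosen after the results were seen, except the 2 on the share of genes moved back. Several gene groups not described above also differed between TBI and Sham. Hippocampal neuron genes rose in 9 of 13 cases in TBI against Sham (9 higher and 2 lower when adjusted over the list alone; median 1.30, camera adjusted p = 7.60e-05; adjusted p = 0.261 with an estimated correlation), including Cabp7 (2.70), C1ql2 (2.94) and Spink8 (2.79), and in 7 of 13 cases in C-β-LG/DSF against Sham (median 1.32). Oligodendrocyte precursor genes rose in 12 of 16 cases (13 higher and 1 lower when adjusted over the list alone; median 0.77, camera adjusted p = 1.36e-05; adjusted p = 0.261 with an estimated correlation), among them Gpr17 (1.28), C1ql1 (1.12) and Olig1 (0.92). Genes of fibroblasts, meninges and extracellular matrix rose in 16 of 24 cases (16 when adjusted over the list alone; median 1.22, camera adjusted p = 1.32e-07; adjusted p = 0.277 with an estimated correlation), including the collagen gene Col3a1 (3.09) and Lum (1.54). Metalloproteinases and their inhibitors rose in 13 of 16 cases (13 when adjusted over the list alone; median 1.29, camera adjusted p = 7.39e-08; adjusted p = 0.261 with an estimated correlation), with Timp1 (4.24) and Mmp2 (1.69) as examples. Oxidative stress and iron handling genes rose in 15 of 27 cases and fell in 2 (18 and 4 when adjusted over the list alone; median 0.74, camera adjusted p = 3.24e-05; adjusted p = 0.261 with an estimated correlation), including the NADPH oxidase subunit gene Cyba (3.13), Rac2 (2.90) and Ncf1 (2.23).

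Aldehyde dehydrogenase genes rose in 5 of 16 cases in TBI against Sham (6 when adjusted over the list alone; median 0.35, camera adjusted p = 0.00514; adjusted p = 0.261 with an estimated correlation), with Aldh1l2 (1.66) and Aldh3b1 (1.37) at the smallest p; in C-β-LG/DSF against TBI 13 of 16 had lower values, 2 of them when adjusted over the list alone, and the list did not pass (median -0.09, camera adjusted p = 0.0664). Interferon response genes rose in 9 of 30 cases and fell in 1 (12 and 1 when adjusted over the list alone; median 0.68, camera adjusted p = 4.83e-05; adjusted p = 0.481 with an estimated correlation), including Irf8 (2.35), Ifi27l2a (3.16) and Ifitm3 (1.93). The list mean was 1.49 in TBI 1 against 0.36 and 0.67 in TBI 2 and TBI 3. The mean difference between C-β-LG/DSF and TBI was -0.28, and 0.04 without TBI 1. Choroid plexus and ependyma genes rose in 5 of 14 cases (7 when adjusted over the list alone; median 1.36, camera adjusted p = 0.000123; adjusted p = 0.288 with an estimated correlation), and their transcript Ttr was at 37.0 FPKM in TBI 1 and 270 FPKM in TBI 3 but 0.13 FPKM in TBI 2. Myelin genes rose in 3 of 20 cases (3 when adjusted over the list alone; median 0.61, camera adjusted p = 0.00739; adjusted p = 0.626 with an estimated correlation), with a mean of 1.92 in TBI 3 against 0.24 and 0.29 in TBI 1 and TBI 2. Of 9 clock genes of the evening phase, chosen after their values were seen, 7 were lower in TBI and 6 in C-β-LG/DSF than in Sham (medians -0.65 and -0.84), with library means of -0.89 to -0.60 in all 6 injured libraries. The 5 clock genes of the opposite phase had medians of -0.23 and -0.12, with 1 lower and none higher in each. Cwc22 was at 25.2, 3.97 and 3.48 FPKM in the C-β-LG/DSF libraries and at 49.9 FPKM or more in the other 6.

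Other lists gave less. Genes of apoptosis and necroptosis rose in 8 of 25 cases and fell in 1 in TBI against Sham (8 and 1 when adjusted over the list alone; median 0.45, camera adjusted p = 0.00214; adjusted p = 0.408 with an estimated correlation), among them Ripk1 (0.95) and Casp6 (0.72), whose calls both ended without Sham 1, without Sham 3 and after quantile normalization; the list mean was 0.78 in TBI 1 against 0.36 and 0.24 in TBI 2 and TBI 3. Endothelium and blood-brain barrier genes rose in 6 of 22 cases (7 when adjusted over the list alone; median 0.35, camera adjusted p = 0.00221; adjusted p = 0.485 with an estimated correlation), including Ly6a (1.97) and the tight junction gene Cldn5 (1.04), whose call ended without Sham 3; the list mean was 0.76 in TBI 1, 0.11 in TBI 2 and 0.50 in TBI 3. Cholesterol synthesis genes did not pass in TBI against Sham (median -0.21, camera adjusted p = 0.12), and had higher values in 17 of 19 cases in C-β-LG/DSF than in TBI (median 0.23, camera adjusted p = 0.00139; adjusted p = 0.565 with an estimated correlation), with Fdft1 (0.37) as an example and no gene passing. Mitochondrially encoded genes had lower values than Sham in all 13 cases in both injured groups, with none called. The list passed in C-β-LG/DSF (median -0.37, camera adjusted p = 0.00115; adjusted p = 0.41 with an estimated correlation) and not in TBI (median -0.27, camera adjusted p = 0.0588). In TBI against Sham the lists of neutrophils (median 0.87, camera adjusted p = 0.0676), pericytes and smooth muscle (0.22, adjusted p = 0.0897), red blood cells (1.81, adjusted p = 0.0793), heat shock and metallothionein (0.04, adjusted p = 0.343), glycolysis and hypoxia (-0.04, adjusted p = 0.719), oxidative phosphorylation (-0.04, adjusted p = 0.444), skeletal muscle (-0.53, adjusted p = 0.51) and striatal neurons (0.11, adjusted p = 0.978) did not pass.

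Thalamic markers were high in 3 of the 6 injured libraries, TBI 3, C-β-LG/DSF 2 and C-β-LG/DSF 3. Hypothalamus and midbrain markers, also chosen after the values were seen, stood there at 2.39, 2.06 and 2.315, against at most 0.34 in the other 6. Deeper tissue in those pieces stays open: in the myelin list, fixed before the data were examined, the lowest of these 3 libraries lay 0.42 above the highest of the other 6, about the Sham SD of 0.43. An exchange of TBI 3 with C-β-LG/DSF 1 stays open too. It would regroup the libraries but would not give a piece these markers, so it is no alternative to deeper tissue. It would raise the count of genes between the 2 injured groups from 0 to 320. That exchange also sets the 3 libraries with thalamic markers against the other injured ones, so the rise could arise without any exchange of labels and does not test it. The pyroptosis list separates the groups as labelled by 0.10. In it TBI 3 (0.75) is the lowest TBI library and C-β-LG/DSF 1 (0.65) the highest C-β-LG/DSF library. Exchanging these 2 turns 0.10 into -0.10 by construction, so this list cannot test the exchange. In thalamic markers as labelled, the lowest C-β-LG/DSF library lay below the highest TBI library (log2 difference -2.20), which speaks against treatment as the cause. These are the same 2 libraries, and the markers were chosen after their values were seen, so treatment stays open while the labels do. The 320 genes were not compared with the thalamic markers.

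Inflammatory and glial lists were lower in C-β-LG/DSF than in TBI. TBI 1 alone stays open as the source: without it the mean difference of the pyroptosis list was -0.27 (-0.50 with it), and the C-β-LG/DSF libraries lay below both other TBI libraries by only 0.10; of all 36 lists 27 were lower on average with TBI 1 and 25 without it. Less injured tissue in the C-β-LG/DSF pieces could give the same picture. It would scale differences in FPKM alike but not those on the log2 scale, where unequal shares can arise from it. The share of the TBI change left (log2) was 53.4% for the pyroptosis list and 86.8% for immediate early genes. The gap was 33.4 percentage points with a jackknife SE of 28.3. Shares on the log2 scale cannot decide this, so less injured tissue stays open. Among the 26 lists that passed in TBI against Sham, the share ran from 32.4% for endothelium through 68.9% for complement to 103.8% for hippocampal genes. These lists were not tested against each other. The spread of the gap was first taken as the range over leaving out 1 library, by which less injured tissue was argued against. It was replaced after that result was seen because that range understates the spread. An effect of C-β-LG/DSF, which the design names, stays open beside these.

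Hippocampal markers were high and cortical layer markers low in both injured groups, with Cabp7 at 34.4 FPKM in TBI against 4.72 FPKM in Sham. Loss of neurons of all kinds would not by itself raise hippocampal markers, whose median change lay 1.86 above that of the general neuron list (log2). This gap restates the pattern that prompted the test, so it cannot show whether such a loss took place. Another part of the brain in the injured pieces, and induction of these genes by the injury, were not tested and stay open.

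With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3836 genes in TBI against Sham (highest other 0; 1 of the splits as large) and 1895 in C-β-LG/DSF against Sham (highest other 0; 1 as large). In C-β-LG/DSF against TBI it gave 0 genes (highest other 320; all 10 as large), and the split with 320 set TBI 3, C-β-LG/DSF 2 and C-β-LG/DSF 3 against the rest, which points to a structure of the samples. For lists the real split gave 26 in TBI against Sham (others 8 to 27, with 2 of the splits as large). It gave 24 in C-β-LG/DSF against TBI (others 16 to 25, with 3 as large). It gave 27 in C-β-LG/DSF against Sham (others 6 to 23, with 1 as large). Splits that mix the groups also pass lists at the preset correlation, so a pass does not by itself show a difference between the groups. The share of genes moved back, 84%, was reached by 5 of the 20 ways to name 3 of the 6 injured libraries TBI (highest other 86.5%) and by 6 of 100 simulations with C-β-LG/DSF equal to TBI, so shared TBI libraries with no effect of treatment remain a possible explanation of it.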
